A study of Mus musculus with 3 samples.

How the data were processed

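Single-cell RNA was measured with a droplet 3' kit in 1 library for each of 3 sorted populations of dorsal root ganglion cells, from 16 mice pooled. Per the submitters' processing notes, Cell Ranger and the mouse build mm10 were used, and per the file headers the software version was 3.0.2. The deposited values are counts of UMIs per gene and barcode, which were checked to be whole numbers without normalisation. A matrix of called cells was used for each library. Matrices of all barcodes, named r1 and r2 by the authors, were used for free RNA and as an alternative. What the names r1 and r2 stand for is not given in the sources used here. For the called cells of the iWAT-labelled and eWAT-labelled libraries r2 was identical to the matrix of called cells, and r1 held a median of 69.1% and 67.4% of a cell's UMIs. For the unlabelled library r1 held 54.1%, and its r2 matrix was not used here. The files list 31053 genes, of which 30934 have their identifier in the GENCODE mouse annotation used for coordinates. Genes with a shared symbol (71) were left out of the gene table of 14971 genes.

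Cells were kept with at least 500 genes and at most 20% mitochondrial UMIs. Of the called barcodes 27.9%, 28.3% and 41.3% in the iWAT-labelled, eWAT-labelled and unlabelled libraries exceeded the mitochondrial limit, and 29.5%, 42.8% and 16.6% had too few genes. Doublets were treated by removing the highest Scrublet scores, 0.8% per 1000 cells in each library, which took out 7, 6 and 65 cells. The 4605 cells of all libraries were clustered together with 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1, and the 3325 neurons were clustered again in the same way. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

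The filters, clustering settings, tests, marker lists, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. No cell annotation was used here, so cell names were rebuilt and may differ from the study's. A cluster was named after the class with the highest mean of its markers, each scaled to its highest cluster, if at least 3 markers were detected at 20 CPM. A neuron cluster stayed unnamed if another class had more markers among its 10 leading genes, or if its median depth was under 1/3 of the library's and it had no own marker there. Any other cluster stayed unnamed if it had no own marker there, or if another class had at least as many. Several choices were made after the data had been seen. The score for naming was first a standardised score and was changed to the fraction of the highest cluster. A cluster with a neuron score of at least 0.2 was taken as neuronal whatever its other scores. This limit was set in the gap between the lowest neuron cluster at 0.241 and the highest other cluster at 0.110. A subtype name required at least 1 own marker among the leading genes, and no other subtype or cell class with more of them there. The naming rule for neurons was relaxed to the score alone for a time and then restored, and values under the score alone are given as an alternative. Which subtypes and lists lead the text was also chosen after the values were seen. A test of posterior Hox genes within shared clusters was added after that with equal weight per subtype, first as 1 sum over the members and then, once that sum was seen, also for the members at 0 apart. A minimum of 20 UMIs in each library was then set for a subtype to count against a shift of spinal levels. Of 28 clusters 20 were neuronal, and the neurons formed 25 clusters, of which 8 took over 80% of their neurons from 1 library.

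UMIs were summed over the neurons of each library and scaled to a common library total (CPM), with exact Poisson intervals. Shares have exact Clopper-Pearson intervals. A ratio between libraries has an exact conditional binomial interval at the 95% level, and a count of 0 was replaced by a floor of 3 counts over the library, which makes the ratio a bound. With 1 library per group there are no p-values and no counts of changed genes. For each pair of libraries the 10 genes with the largest ratio each way were named, among genes with at least 100 UMIs over both libraries, a UMI in at least 5% of the neurons of the higher library and a level above that of its non-neuronal cells. Mitochondrial, ribosomal protein, haemoglobin and unnamed genes were left out. Piezo2 and the extreme members of each list were named in addition. List medians used members with at least 20 UMIs over the pair, with intervals from 1000 Poisson draws, and were set beside 10000 random lists matched on mean expression. The lists were mechanically gated or modulating channels, TRP channels, neuropeptides, neurotrophic receptors, voltage-gated sodium and potassium channels, metabolic hormone and adipokine receptors, lipid and fatty acid sensing, itch receptors, axon injury, dissociation stress and immediate early genes, anterior, middle and posterior Hox genes, oxidative phosphorylation and adipocyte markers. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs.

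The ratio and list steps were tested on simulated counts in which 200 genes had been changed 2-fold. These counts were Poisson draws of library sums without variation between neurons, as the intervals assume. The check thus covers the code, and not whether the intervals are wide enough for real neurons. For iWAT-labelled over unlabelled neurons (14663 genes) the intervals held the true ratio for 95.6% of unchanged genes, 97.0% of genes made higher and 96.0% of genes made lower. For eWAT-labelled over unlabelled neurons (14639 genes) these were 95.7%, 94.0% and 95.0%, and for iWAT-labelled over eWAT-labelled neurons (13756 genes) 95.7%, 97.0% and 99.0%. A first draw of 1 unchanged list per pair gave percentiles near the ends of the range, so 200 lists were drawn in its place. Of these lists of 15 unchanged genes, 3.00%, 4.00% and 6.00% fell outside the central 95% of random lists in the 3 pairs, and all of 20 lists of genes made 2-fold higher did.

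Alternatives changed the cell filter, doublet removal, the clustering resolution, the naming of cells and subtypes, the scaling, the weight of subtypes, the count minimum of lists and the count matrix. Free RNA was estimated from barcodes of under 100 UMIs and scaled by markers of other cell types. This correction set the free RNA to be subtracted at 99.3%, 41.6% and 50.4% of all neuronal UMIs in the iWAT-labelled, eWAT-labelled and unlabelled libraries. That amount was spread over genes by the estimated profile. In the iWAT-labelled library the estimates by marker class ran from 44.9% to 154%, so there the correction subtracts too much and its values are given only as an extreme. In the eWAT-labelled and unlabelled libraries they ran from 2.17% to 96.4% and from 7.85% to 81.5%, so the correction is uncertain there too. Added after the data had been seen were neurons of at least 5000 UMIs, leaving out clusters mostly of 1 library, and naming neurons by score alone.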

Results

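Dorsal root ganglia hold the cell bodies of the sensory neurons that carry touch, pain, itch and temperature from the body. The series asked which of these neurons reach white fat, and its title names PIEZO2, an ion channel opened by mechanical force. Per the labels, male mice received cholera toxin B, a tracer carried back along axons to the cell body, in 2 depots. The dye CTB488 went into inguinal white adipose tissue (iWAT), the fat under the skin of the flank, and CTB647 into epididymal white adipose tissue (eWAT), a fat pad of the abdomen. Ganglia of 16 mice were pooled and sorted into cells with the first dye, cells with the second dye and cells with neither, here called iWAT-labelled, eWAT-labelled and unlabelled. Each sort gave 1 single-cell RNA library, so the 3 libraries have no replicates, no test between groups was possible, and each difference is one between libraries. Intervals are at the 95% level and cover counting error only.

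The deposited matrices of called cells held 1989 barcodes and 20107245 unique molecular identifiers (UMIs, counted molecules) for the iWAT-labelled library. The eWAT-labelled library had 1979 barcodes and 14748186 UMIs, and the unlabelled library 5895 barcodes and 62265275 UMIs. After filtering, 957, 858 and 2790 cells remained, of which 842, 635 and 1848 were sensory neuron-like. These neurons held 15023981, 9959402 and 38518024 UMIs, with medians of 2896, 4013 and 3061.5 per neuron. Neurons of at least 5000 UMIs supplied 95.1%, 92.2% and 96.2% of the neuronal UMIs, so summed values mostly describe the deeper 365, 281 and 839 neurons.

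Sensory neuron-like cells made up most of each library. Their share was 88.0% (exact binomial interval 85.8 to 90.0) in the iWAT-labelled, 74.0% (70.9 to 76.9) in the eWAT-labelled and 66.2% (64.4 to 68.0) in the unlabelled library. Satellite glia-like cells, which wrap neuronal cell bodies, made up 5.43%, 7.93% and 12.2%. Myelinating Schwann cell-like cells made up 1.04%, 1.17% and 4.48%, and fibroblast-like cells 0.209%, 0.816% and 2.54%. Endothelial-like cells were 3.73% of the eWAT-labelled and 2.22% of the unlabelled library. None of the 957 iWAT-labelled cells was endothelial-like, which allows a share of up to 0.313%, taken as 3 counts of that total. Pericyte or smooth muscle-like cells made up 0.313%, 2.56% and 1.0%. The rest, 5.02%, 9.79% and 11.4%, stayed unnamed, in clusters led by S100a9, by Neat1 and by Pou3f1. The sort gates and the filters set these shares in part. With cells named 1 by 1, the neuron share eWAT-labelled cells gave was 49.9%, below the neuron share unlabelled cells gave, 59.5%.

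Among neurons, C low-threshold mechanoreceptor-like cells, a class of unmyelinated touch neurons named here from genes such as P2ry1, Bok and Slc17a8, were most frequent in the iWAT-labelled library. They formed 20.7% (18.0 to 23.6) of iWAT-labelled, 8.50% (6.45 to 10.9) of eWAT-labelled and 13.3% (11.8 to 14.9) of unlabelled neurons. Peptidergic small-diameter-like neurons, which carry transcripts of pain-related neuropeptides, formed 24.6% (21.7 to 27.6), 6.93% (5.08 to 9.19) and 18.7% (17.0 to 20.6). Peptidergic A-delta-like neurons formed 3.21%, 5.20% and 3.03%, and Trpm8 cold-sensing-like neurons 3.56%, 3.94% and 1.84%. Across alternatives the Trpm8-like shares ran from 1.66% to 10.5%, from 2.52% to 26.1% and from 0.379% to 7.47%. The A-delta-like shares reached 8.31%, 13.9% and 9.69%, and were 0% with doublets kept and at resolution 0.5. Non-peptidergic neurons like those with the receptor gene Mrgprd formed 9.52% (8.22 to 11.0) of unlabelled neurons, against 0.713% (0.262 to 1.54) and 0.315% (0.038 to 1.13) of the iWAT-labelled and eWAT-labelled ones. With subtypes named neuron by neuron they formed 13.0%, 6.41% and 2.21%. Mrgpra3-like neurons formed 2.73% of iWAT-labelled and 2.54% of unlabelled neurons. None of 635 eWAT-labelled neurons was of this type, which allows up to 0.472% on the same basis. With subtypes named neuron by neuron the Mrgpra3-like shares were 10.8%, 2.05% and 9.69%, and under the looser filter the unlabelled share was 15.5%. Sst or Nppb-like neurons formed 0.119%, 0.157% and 1.79%, and 6.06%, 4.57% and 8.17% when named neuron by neuron.

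A large part of the neurons, 44.4%, 75.0% and 49.2%, stayed without a subtype name. Markers were also fixed for A-fibre low-threshold mechanoreceptors and for proprioceptors, but no cluster took either name. Such neurons, if present, thus have no share or Piezo2 level of their own here. The largest unnamed cluster of the unlabelled library, led by AY036118, Lars2 and Gm42418, held 22.0% of unlabelled, 9.74% of iWAT-labelled and 6.14% of eWAT-labelled neurons, with a median of 867 UMIs. These shallow neurons count in the denominator of every subtype share. The largest cluster of the eWAT-labelled library, led by Gm26917, Gm4117 and Col6a5, held 34.2% of eWAT-labelled, 2.85% of iWAT-labelled and 1.30% of unlabelled neurons. Its neurons count in that denominator too. A cluster led by Itga1, Tmc3 and Klhl1 held 7.56%, 3.21% and 1.57% of the eWAT-labelled, iWAT-labelled and unlabelled neurons, and a cluster led by Col11a1 and Rgs6 held 8.03%, 2.38% and 4.06%. A cluster led by Sprr1a and Atf3, genes induced by nerve injury, held 3.21% of iWAT-labelled, 0.157% of eWAT-labelled and 0.649% of unlabelled neurons. A cluster led by Gm567 and Cav2 held 14.0% of iWAT-labelled, 0.315% of eWAT-labelled and 0.433% of unlabelled neurons, with a median of 1162 UMIs. Gm567 and Smyd3 are among the 10 leading genes of both this cluster and the Mrgpra3-like one. The Mrgpra3-like shares may thus leave out shallow neurons of that type, which was not tested. With 1 library per group, a cluster mostly of 1 library can reflect that library and not a cell type. A cluster led by Apoc1 and Apoe, the latter a gene of satellite glia, held 2.97%, 2.99% and 5.41% of the iWAT-labelled, eWAT-labelled and unlabelled neurons. The peptidergic small-diameter-like neurons came from different clusters. One led by Adra2a and Chrna3 held 1 iWAT-labelled, 25 eWAT-labelled and 100 unlabelled neurons, and one led by Pcp4l1 and Kcnv1 held 88, 1 and 12. The share of this subtype moved by over 1.5 times between settings, and under the looser cell filter it was 10.5% in the iWAT-labelled and 19.5% in the eWAT-labelled library.

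**Figure D1:**
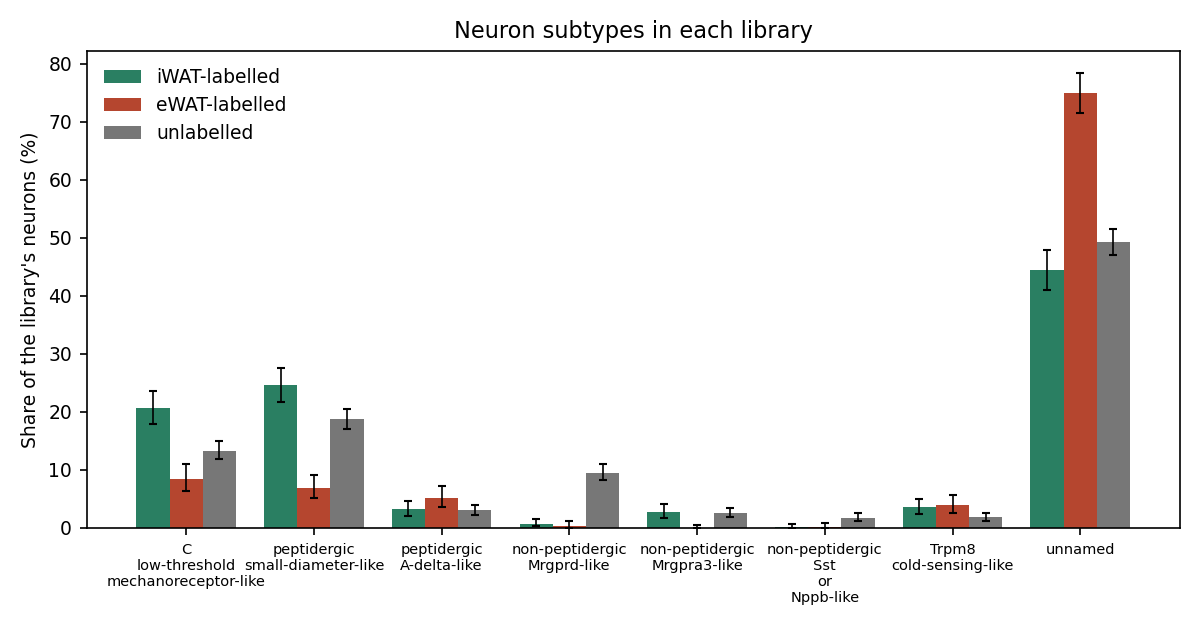
Share of each library's neurons (percent) in each named subtype, with the iWAT-labelled, eWAT-labelled and unlabelled libraries as separate bars and exact binomial 95% intervals for counting error. C low-threshold mechanoreceptor-like neurons stand at 20.7%, 8.50% and 13.3%, and unnamed neurons at 44.4%, 75.0% and 49.2%.

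Piezo2 was detected in the neurons of all 3 libraries, at a somewhat higher level in both labelled libraries than in the unlabelled one. The gene (ENSMUSG00000041482, protein-coding) lies on the minus strand of chromosome 18, from 63010213 to 63387183 in mm10. Its summed level was 358.2 CPM (UMIs of the gene scaled to a common library total) (348.7 to 367.9) in iWAT-labelled, 333.0 (321.7 to 344.5) in eWAT-labelled and 284.4 (279.1 to 289.7) in unlabelled neurons. The ratio over unlabelled neurons was 1.26 (1.22 to 1.30) for iWAT-labelled and 1.17 (1.13 to 1.22) for eWAT-labelled neurons. As a mean over cells the iWAT-labelled ratio was 1.01, and under the looser filter the eWAT-labelled ratio was 0.954. With free RNA subtracted, a correction that removes too much in the iWAT-labelled library, the iWAT-labelled ratio was 2.22. The ratio of iWAT-labelled over eWAT-labelled neurons was 1.08 (1.03 to 1.12), but its direction was not stable: it was 0.785 as a mean over cells, 0.870 under the stricter filter and 0.936 with equal weight per subtype.

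Piezo2 differed far more between subtypes than between libraries. It stood at 1025 (990.5 to 1060.0), 1333 (1263 to 1406) and 899.6 (874.0 to 925.7) CPM in C low-threshold mechanoreceptor-like neurons of the iWAT-labelled, eWAT-labelled and unlabelled libraries. Piezo2 is itself 1 of the markers fixed for this subtype, so its high level there is partly by construction. In the unnamed cluster led by Col11a1 and Rgs6, which Piezo2 did not name, it reached 1676 (1423 to 1960), 1848 (1713 to 1990) and 1295 (1141 to 1463). Peptidergic A-delta-like neurons held 519.1, 358.3 and 342.4, and unlabelled Mrgprd-like neurons 478.5. Peptidergic small-diameter-like neurons held 53.2, 13.2 and 34.4, and Trpm8 cold-sensing-like neurons 17.4, 20.9 and 9.37, against 15.1, 17.5 and 15.1 in satellite glia-like cells. After each neuron was thinned to 2000 UMIs, 36.8% (32.4 to 41.4), 34.2% (29.8 to 38.8) and 32.7% (29.9 to 35.7) had a Piezo2 UMI, with overlapping intervals. Across alternatives, 1 of which required at least 2 UMIs, these shares ran from 19.7% to 43.2%, from 22.2% to 37.0% and from 18.3% to 36.0%. In thinned satellite glia-like cells the shares were 4.0%, 1.47% and 2.10%. Without thinning, 43.9%, 37.5% and 44.8% of neurons had a Piezo2 UMI, and 11.5%, 11.8% and 13.9% of satellite glia-like cells, whose median depths were 7965.5, 9570.0 and 9321 UMIs. Thinning left out 380, 190 and 806 shallower neurons.

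**Figure D2:**
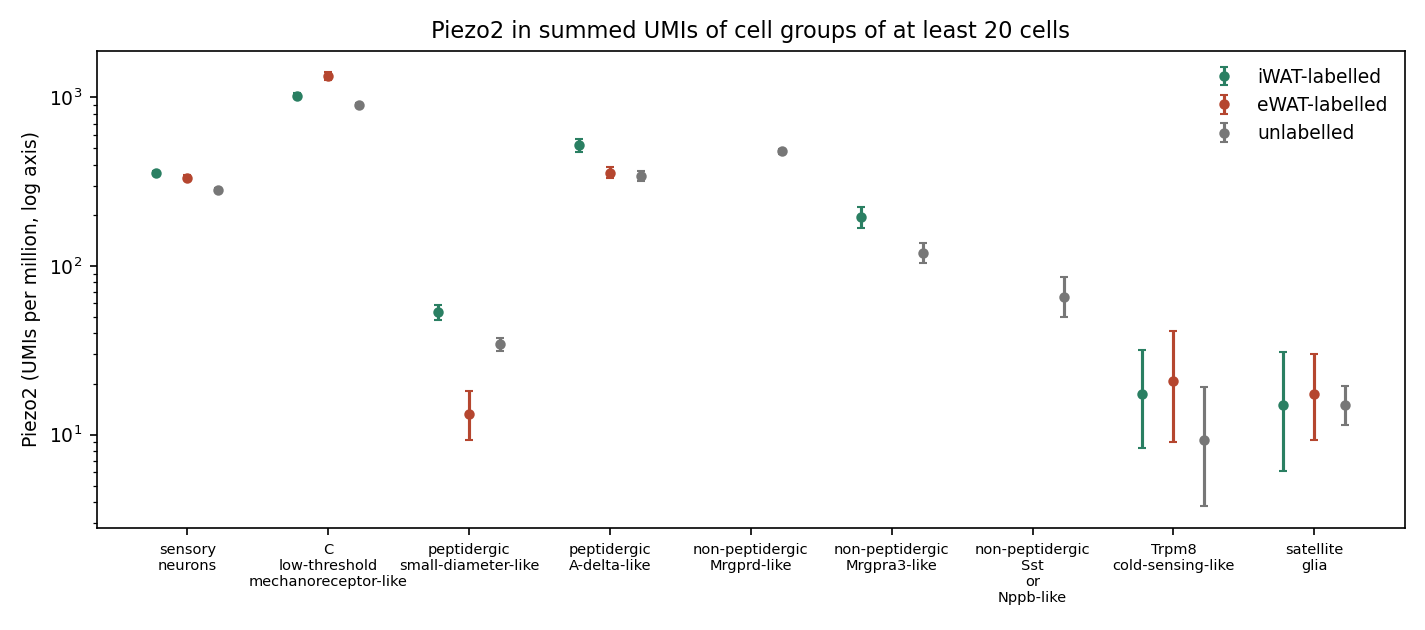
Piezo2 level (CPM, log axis) in summed UMIs of all neurons, of each subtype with at least 20 cells in a library, and of satellite glia, one point per library with exact Poisson 95% intervals. C low-threshold mechanoreceptor-like neurons lie between 899.6 and 1333, and satellite glia between 15.1 and 17.5.

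Gene lists fixed beforehand were compared by the median log2 ratio of their measured members, set beside 10000 random lists of equal size and similar expression. The median over all genes was -0.03 for iWAT-labelled over unlabelled neurons, 0.13 for eWAT-labelled over unlabelled and -0.17 for iWAT-labelled over eWAT-labelled, and each percentile is relative to its own random lists, whose medians differ from that shift.

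Compared with unlabelled neurons, iWAT-labelled neurons held more transcript of axon injury genes and less of itch receptor and posterior Hox genes. Of 17 measured injury genes 9 were at least 1.5-fold higher and 1 at least 1.5-fold lower, with a median log2 ratio of 0.70 (0.34 to 0.80) above all random lists. Atf3, a transcription factor induced in injured neurons, was 4.44-fold higher (4.10 to 4.82) and the semaphorin Sema6a 3.53-fold (2.90 to 4.31), whereas Sprr1a stood at a ratio of 0.841 (0.766 to 0.922). For Sprr1a, 1 neuron held 64.3% of the iWAT-labelled and 1 held 77.8% of the unlabelled UMIs, and 5.46% and 1.25% of neurons had a UMI. Npy was 16.2-fold higher (4.34 to 136) in unlabelled neurons, on 2 against 83 UMIs, and 1 neuron held 72.3% of the latter. A single iWAT-labelled neuron held 23.1% of the Atf3 UMIs. Dissociation stress and immediate early genes, a list that also holds Atf3 and Jun, had a median of 0.21 (0.10 to 0.28) at percentile 99.9, with Socs3 at 2.0 (1.68 to 2.38) and Fosb at 0.424 (0.246 to 0.692).

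Of 13 itch receptor genes 8 were at least 1.5-fold lower in iWAT-labelled than in unlabelled neurons and 0 higher, with a median of -1.03 (-1.38 to -0.90), below all random lists. The median was -1.78 under the looser filter, -0.31 with equal weight per named subtype and -0.21 without clusters mostly of 1 library. Nppb, a peptide of itch neurons, was 12.6-fold higher (8.38 to 19.7) in unlabelled neurons, with 66.7% of its 24 iWAT-labelled UMIs in 1 neuron, while the cytokine receptor gene Il4ra stood at 1.41 (1.30 to 1.52). Posterior Hox genes, transcription factors that mark lower body levels in development, had a median of -2.10 over 5 measured members, 3 of them at the bound that a count of 0 allows, so that the floor sets this median, and -3.58 with equal weight per subtype. Hoxd10 (chromosome 2, 74691924 to 74695105, plus strand) and Hoxd11 (74679557 to 74687016, plus strand) had 0 UMIs in iWAT-labelled neurons against 187 and 217 in unlabelled ones. They were thus at least 24.3-fold and 28.2-fold lower, set against a floor of 3 counts over the library. Hoxa10 and Hoxc10 stood at 0.683 (0.592 to 0.785) and 0.628 (0.479 to 0.814).

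Among genes that met the rule for naming, Ly6a had the largest ratio in iWAT-labelled over unlabelled neurons, at 8.45 (7.0 to 10.2). The activin-binding protein gene Fst at 7.18 (5.99 to 8.65) and the metalloproteinase inhibitor gene Timp1 at 6.05 (5.09 to 7.21) came next. Sez6l, Atf3, the cold-activated channel gene Trpm8 (3.91), Wnt11 (3.56), Pcp4l1 (3.36), the carbonic anhydrase gene Car12 (3.25) and Col25a1 (3.03) followed. Ly6a is also 1 of the endothelial markers, and the 12 endothelial markers together stood at 132 CPM in iWAT-labelled and 90.4 in unlabelled neurons. In iWAT-labelled cells outside the neuron clusters, none of them endothelial-like, these markers stood at only 16.9 CPM. The rule of a level above that of non-neuronal cells thus could not screen out endothelial RNA in this library. Wnt11 turned to 0.810 once free RNA was subtracted, Sez6l was at 1.33 with equal weight per subtype, and as a mean over cells Car12 was at 1.31 and Col25a1 at 1.94. Higher in unlabelled neurons were the nicotinic receptor subunit gene Chrna3, 11.7-fold (9.69 to 14.2), the matrix proteoglycan gene Vcan, 10.3-fold (7.59 to 14.4), the angiotensin receptor gene Agtr1a (8.89), Cysltr2 (7.50), and the oestrogen receptor gene Esr1 and the adrenergic receptor gene Adra2a (both 7.12). Kctd4, Otoa, Mrgprd and Nog were 6.44-fold, 6.09-fold, 5.87-fold and 5.85-fold higher, with 75.0% of the 24 iWAT-labelled Otoa UMIs in 1 neuron. Chrna3, Vcan and Adra2a lead the peptidergic cluster that held 1 iWAT-labelled neuron, and Mrgprd, Agtr1a and Otoa lead clusters of Mrgprd-like neurons. The ratio of Agtr1a was 0.525 with equal weight per subtype, and that of Esr1 was 0.537 once free RNA was subtracted.

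The remaining lists lay as follows between iWAT-labelled and unlabelled neurons. Metabolic hormone and adipokine receptors had a median of -0.25 (percentile 0.22), with the cholecystokinin receptor gene Cckbr at 5.04 and Npy1r at 2.13 but Adra2a at 0.141. In the clustering of all cells, Cckbr was among the 10 leading genes of a cluster led by Sprr1a. That cluster held 2.93% of iWAT-labelled and 0.502% of unlabelled cells. Lipid and fatty acid sensing genes had -0.32 (percentile 0.85), anterior Hox genes -0.27 (2.53), TRP channels -0.15 (4.26) and neurotrophic receptors -0.11 (10.2). Mechanically gated or modulating channels had -0.03 (44.7), neuropeptides -0.03 (41.6), voltage-gated potassium channels -0.04 (43.2), voltage-gated sodium channels -0.01 (59.6), middle Hox genes -0.02 (54.4) and oxidative phosphorylation genes -0.02 (49.3). Each of these last 6 medians changed sign under at least 1 alternative, and all of them except that of the potassium channels under median-of-ratios scaling, which shifts every gene of a pair by the same amount. Medians this near 0 give no direction. The TRP channel and neurotrophic receptor medians changed sign with equal weight per subtype. Cck was 20-fold higher (7.88 to 65.0) in iWAT-labelled neurons on 39 against 5 UMIs, and Sst had 0 against 561 UMIs.

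Compared with unlabelled neurons, eWAT-labelled neurons held less transcript of itch receptor and neuropeptide genes. Of 13 itch receptor genes 10 were at least 1.5-fold lower and 0 higher, with a median of -2.01 (-2.41 to -1.80), and of 14 neuropeptide genes 10 were lower and 0 higher, with a median of -1.11 (-1.36 to -0.88). Both medians lay below all random lists, and with equal weight per named subtype they were -0.40 and -0.35. Mrgpra3 had 1 UMI against 684, a ratio of 177 (31.6 to 6996) towards unlabelled neurons, and Mrgprd was 13.9-fold higher (11.0 to 17.9) there, with 68.1% of its 69 eWAT-labelled UMIs in 1 neuron. Sst had 0 UMIs against 561, at least 48.4-fold lower, while Gal and Adcyap1 stood at 1.16 and 1.10. Oxidative phosphorylation genes were lower, with a median of -0.51 (-0.59 to -0.44) at percentile 0.33 and 6 of 14 members at least 1.5-fold lower, among them Cox5a at 0.524. Over 9 alternatives this median ran from -0.64 to -0.40. The cluster with 34.2% of the eWAT-labelled neurons had a ribosomal protein share 0.264 times and a nuclear RNA share 1.48 times that of other eWAT-labelled neurons of similar depth. The oxidative phosphorylation median stayed in that range also in the alternatives that leave this cluster out. Voltage-gated sodium channels had a median of 0.36 (0.31 to 0.47) at percentile 98.3. Within that list the gene Scn3a stood at 2.29 (2.04 to 2.58), whereas Scn10a and Scn11a, channels of pain-sensing neurons, stood at 0.640 (0.615 to 0.665) and 0.498 (0.473 to 0.523).

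Among genes that met the rule for naming, Grid2ip had the largest ratio of eWAT-labelled over unlabelled neurons, at 11.2 (7.20 to 17.9). The calcium pump gene Atp2a3 at 9.34 (7.63 to 11.5), Tmc3 at 9.33 (7.54 to 11.6), Creb5 at 9.02 and the integrin gene Itga1 at 8.19 (7.18 to 9.35) came next. Col25a1 (7.48), Klhl1 (7.14), Arsj (6.69), Doc2b (6.28) and the calcium channel gene Ryr3 (6.15) followed. Most of these lead the Itga1 cluster or the Col11a1 cluster, and Grid2ip turned to 0.733 with equal weight per named subtype, which leaves those clusters out. With that weight Atp2a3, Itga1, Klhl1 and Ryr3 were at 1.21, 1.44, 1.88 and 1.39, and Ctxn3, named next, at 0.853. Higher in unlabelled neurons were Serpina11, 78.5-fold (21.6 to 650) on 2 against 607 UMIs, and Slc16a12, 29.99-fold (10.2 to 146) on 3 against 348 UMIs. Krt27 (19.9), Ctxn3 (15.8), Ms4a3 (15.8), Nnat (14.0), Nog (13.3), Arhgap36 (11.8) and Tmem233 (11.3) were also higher there. Serpina11, Ctxn3 and Nnat lead a cluster of Mrgprd-like neurons that held 33 unlabelled and 0 eWAT-labelled neurons.

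Among the other lists, mechanically gated or modulating channels had a median of -0.09 (-0.17 to 0.09) in eWAT-labelled over unlabelled neurons, at percentile 5.01, with members on both sides. The chloride channel gene Ano1 stood at 5.35 (3.37 to 8.57), with all 47 eWAT-labelled UMIs in 1 neuron, and the potassium channel gene Kcnk2 at 2.42 (2.31 to 2.54), whereas Tmem45b and Kcnk18 stood at 0.207 and 0.199. TRP channels had a median of 0.39 (percentile 95.9), with Trpm8 at 4.11 and Trpc6 at 0.100. Injury genes had -0.10 (10.9), stress genes -0.01 (10.4), neurotrophic receptors -0.12 (38.7), potassium channels -0.05 (21.1), metabolic hormone and adipokine receptors 0.04 (25.4) and lipid and fatty acid sensing genes -0.09 (14.3). Each of these 6 changed sign under at least 1 alternative, the metabolic receptors also under median-of-ratios scaling. The mechanically gated channel median was 0.00 without clusters mostly of 1 library. Anterior, middle and posterior Hox genes had 0.41 (74.1), 0.35 (76.0) and 0.58 (85.8), and the posterior median turned to -0.62 with equal weight per subtype.

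Set against each other, iWAT-labelled neurons held more transcript of injury, neuropeptide and itch receptor genes than eWAT-labelled neurons, and eWAT-labelled neurons held more of the posterior Hox genes, 3 of which had no UMI in iWAT-labelled neurons. Injury genes had a median of 0.86 (0.71 to 0.99), above all random lists, with 10 of 15 at least 1.5-fold higher and 0 lower. Sprr1a was 134-fold higher (45.8 to 653), on 608 against 3 UMIs, but 64.3% of its iWAT-labelled UMIs came from 1 neuron. Nts, which encodes neurotensin, was 23.8-fold higher (15.8 to 37.8), but 1 neuron held 51.5% of its iWAT-labelled and 1 held 87.0% of its 23 eWAT-labelled UMIs. Neuropeptide genes had a median of 0.54 (0.46 to 0.99) at percentile 99.5, with Cartpt at 0.492, and itch receptor genes 0.59 (0.39 to 0.91) at percentile 99.98, with Mrgpra3 at 182 (32.5 to 7226) on 275 against 1 UMI. The itch receptor median was 1.29 under the looser filter and 0.19 with equal weight per subtype. Posterior Hox genes had a median of -3.59, below all random lists, again with 3 of 5 measured members at the bound of a count of 0. The floor of 3 counts thus sets this median, which belongs to Hoxc11 with 0 against 24 UMIs. Hoxa10, the most abundant member, stood at 0.795 (0.659 to 0.959) and Hoxc10 at 0.576 (0.415 to 0.798). Hoxd10 and Hoxd11 had 90 and 84 UMIs in eWAT-labelled neurons, so that they were at least 45.3-fold and 42.2-fold lower in iWAT-labelled neurons. Within peptidergic small-diameter-like neurons the summed posterior Hox level had a ratio of 0.232 (0.183 to 0.293), but different clusters made up this subtype. The Adra2a and Chrna3 cluster held 1 iWAT-labelled and 25 eWAT-labelled neurons, the Pcp4l1 cluster 88 and 1, and the cluster led by Ccl2 68 and 7. Within Trpm8 cold-sensing-like neurons the ratio was 2.85 (1.23 to 7.69), on 30 against 7 UMIs. In the 8 clusters with at least 20 neurons of both labelled libraries, the summed posterior Hox UMIs of iWAT-labelled neurons were 1.06 (0.816 to 1.34) times those expected from eWAT-labelled neurons of the same clusters. This sum hid members that went apart. Hoxa10 and Hoxc10 had 105 UMIs against 73.1 expected, and the 3 members at 0 had none against 25.8 expected.

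Higher in iWAT-labelled than in eWAT-labelled neurons were also Krt27 at 18.0 (9.65 to 38.0), Timp1 at 17.4 (10.7 to 30.1), Fgg at 12.9, the chemokine gene Ccl2 at 10.6 (7.30 to 16.1), Ly6a at 9.90, Fst at 9.71, the vasopressin receptor gene Avpr1a at 7.91, Plaur at 7.54 and Igfbpl1 at 6.70. Timp1 turned to 0.598 after free RNA was subtracted, and 1 neuron held 65.6% of the 32 eWAT-labelled Ly6a UMIs. Ccl2, Avpr1a and Igfbpl1 lead a peptidergic cluster that held 68 iWAT-labelled and 7 eWAT-labelled neurons. Higher in eWAT-labelled neurons were Otof, 149-fold (26.2 to 5958) on 99 against 1 UMI, Cntn5, 20.9-fold (10.7 to 46.9), Vcan, 20.4-fold (14.9 to 28.7), and Esr1, 15.3-fold (10.5 to 23.3). Tc2n (10.6), the fibrillin gene Fbn2 (10.1), Vmn1r89 (9.24), Zfp114 (8.91), Chrna3 (8.69) and the collagen gene Col6a5 (8.36) followed. With equal weight per subtype the ratio of iWAT-labelled over eWAT-labelled neurons was 1.88 for Plaur, 0.536 for Zfp114 and 0.738 for Col6a5.

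Oxidative phosphorylation genes had a median of 0.44 (0.39 to 0.50) for iWAT-labelled over eWAT-labelled neurons, at percentile 97.9, and of 0.16 with equal weight per subtype, with Cox5a at 2.11. Lipid and fatty acid sensing genes had 0.34 (97.46), but -0.07 with equal weight per subtype, and stress genes 0.25 (99.8), but -0.10 with equal weight per subtype. Mechanically gated or modulating channels had 0.07 (-0.03 to 0.15) at percentile 94.1, with Tmem45b at 3.26 and Kcnk2 at 0.430, and potassium channels 0.04 (85.7). Both medians were below 0 under the stricter filter. Neurotrophic receptors had 0.06 (55.4), with the brain-derived neurotrophic factor receptor gene Ntrk2 at 0.341 (0.316 to 0.368), and changed sign with equal weight per subtype. Sodium channels had -0.16 (24.6), which turned to 0.01 under median-of-ratios scaling, TRP channels -0.36 (7.91) and metabolic hormone and adipokine receptors -0.24 (34.0). Anterior and middle Hox genes had -0.47 (20.6) and -0.37 (26.4). Adipocyte markers had fewer than 3 measured members in each comparison and were given no median.

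**Figure D3:**
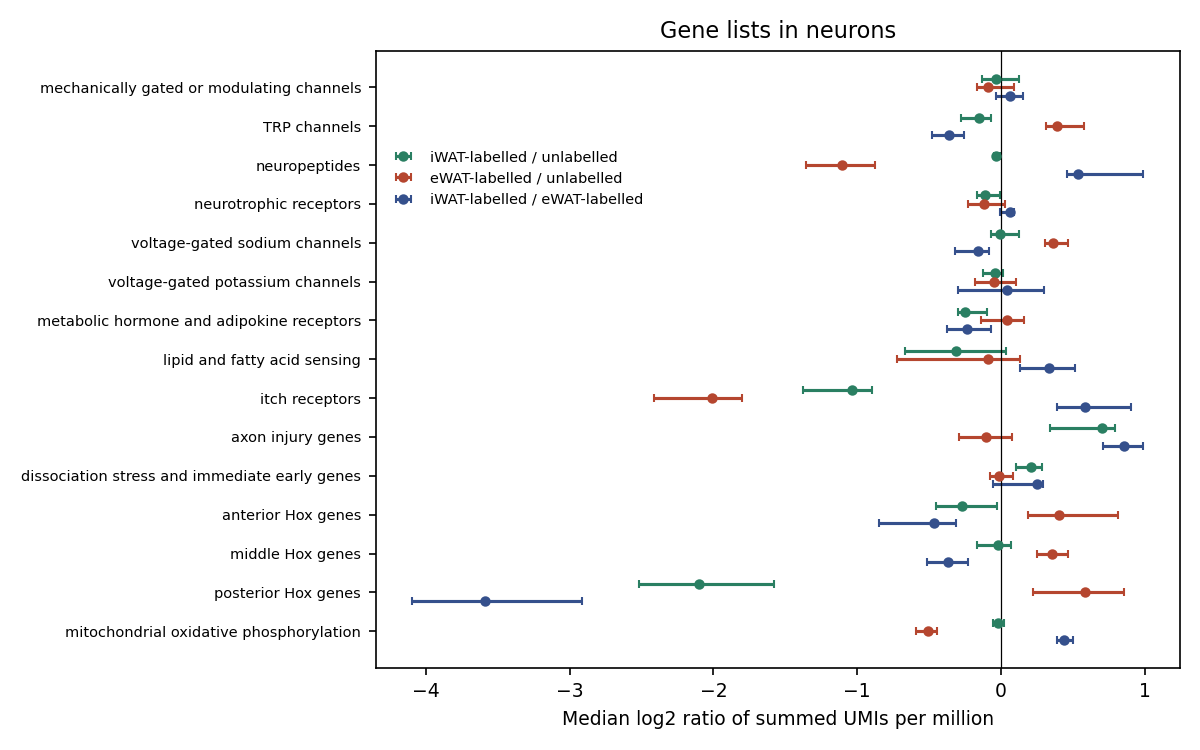
Median log2 ratio of summed CPM for each gene list in neurons, one point for each pair of libraries, with 95% intervals for counting error only. Posterior Hox genes lie at -2.10, 0.58 and -3.59, the first and last set by the floor for a count of 0, and axon injury genes at 0.70, -0.10 and 0.86, for iWAT-labelled over unlabelled, eWAT-labelled over unlabelled and iWAT-labelled over eWAT-labelled neurons.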

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

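The tests of dissociation stress, of posterior Hox genes within clusters and of free RNA for the members at 0 were chosen only after the result was seen, as were the reasons given for leaving open the makeup of subtypes and the spinal levels, which the criteria set beforehand had counted as excluded.

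The iWAT-labelled share of C low-threshold mechanoreceptor-like neurons was 2.43 times the eWAT-labelled share, and that of peptidergic small-diameter-like neurons was 3.55 times. In both cases the iWAT-labelled share lay above and the eWAT-labelled share below the unlabelled one, but for the peptidergic neurons this order turned in several alternatives. Their shares were 34.2%, 15.3% and 38.9% in neurons of at least 5000 UMIs, and 10.5%, 19.5% and 14.6% under the looser filter. All these are shares of all neurons, of which 44.4%, 75.0% and 49.2% of the iWAT-labelled, eWAT-labelled and unlabelled ones had no subtype name. The low eWAT-labelled shares of both subtypes may thus reflect the larger unnamed part of that library. Shares among named neurons only were not computed. Neither difference was tested, since each group is 1 library. Piezo2 was also counted in barcodes that were not called as cells, with 4707 UMIs for the iWAT-labelled library and 1699 for the eWAT-labelled library in the matrix named r2, and 2593 for the unlabelled library in r1.

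Posterior Hox genes were lower in iWAT-labelled than in eWAT-labelled neurons, far lower for the 3 members at 0, and at 0.795 and 0.576 for Hoxa10 and Hoxc10. The tables argue against free RNA as the whole cause. The summed level of these genes in near-empty barcodes of the eWAT-labelled library was 0.652 (0.456 to 0.907) times that in its neurons. For the 3 members at 0 alone it was 0.768 (0.446 to 1.246), which does not exclude it, but in 1 of 4 subtypes, the peptidergic small-diameter-like neurons, they stood at 2.62 (1.58 to 4.57) times the near-empty level, on 112 UMIs, more than free RNA alone can give. A different makeup of subtypes stays open. The median log2 ratio with equal weight per named subtype was -3.17, but 3 of the 5 members had 0 UMIs in iWAT-labelled neurons, so no weight can lift that median from its floor. A different makeup of clusters stays open for Hoxa10 and Hoxc10, which had 105 UMIs in the 8 shared clusters against 73.1 expected. That is a ratio of 1.436 (1.109 to 1.863), so within these clusters their sum was higher, not lower, in iWAT-labelled neurons. For the 3 members at 0 the counts in these clusters argue against a different makeup of clusters as the whole cause. They had 0 UMIs in the 331 iWAT-labelled neurons of these clusters against 25.8 expected, from 23 of 477 eWAT-labelled neurons. None of these clusters was peptidergic small-diameter-like. In eWAT-labelled C low-threshold mechanoreceptor-like and A-delta-like neurons the 3 members stood at 0.521 (0.196 to 1.26) and 1.496 (0.845 to 2.756) times the near-empty level. Trpm8 cold-sensing-like neurons had 0 of their UMIs. Part of the expected UMIs may thus be free RNA, and free RNA together with a different makeup stays open. The summed ratio of 1.061 (0.816 to 1.343) mixes members that went apart, so it cannot decide. Other spinal levels also stay open, as an assumption, since the labels give no spinal level per depot. Of 4 subtypes 1 had its interval below 1, the peptidergic small-diameter-like neurons, whose clusters differed. The C low-threshold mechanoreceptor-like neurons at 0.741 (0.497 to 1.126) and the A-delta-like neurons at 0.839 (0.583 to 1.191) had intervals that held 1. The Trpm8 cold-sensing-like neurons went the other way at 2.85 (1.23 to 7.69), on 7 eWAT-labelled UMIs, too few to exclude it.

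Axon injury genes were higher in iWAT-labelled than in unlabelled neurons. Dissociation stress as the whole cause is argued against by the 18 stress genes outside the injury list, whose median log2 ratio was 0.143 (0.049 to 0.234), below the injury list's interval. A single small cluster led by Sprr1a is argued against by the median of 0.741 (0.616 to 0.817) without that cluster. Injury of axons by the injection, or a difference between the depots, may contribute, and neither was tested. In eWAT-labelled neurons, whose depot was also injected, the injury median over unlabelled neurons was -0.102 (-0.294 to 0.077). Each depot had its own dye and sort, so depot, dye and sort cannot be told apart.

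A neuron cluster led by Gm26917 and Gm4117 held 217 eWAT-labelled neurons and 24 in each other library. Free RNA is argued against by 2463 genes at least 2-fold higher in the cluster, whose level in near-empty barcodes was a median of 0.633 (0.610 to 0.637) times that in other neurons. Cells that lost cytoplasm cannot be told apart from a neuron type. Among neurons of similar depth (159 and 104), the ribosomal protein share was 0.264 (0.254 to 0.275) times that of other eWAT-labelled neurons, as lost cytoplasm requires. The nuclear RNA share was 1.48 (1.47 to 1.49) times as high, just under the 1.5 required, which keeps the question open. The median mitochondrial percent was 2.045 in the cluster and 2.003 in the others.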

How the results depend on the processing

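The values for neurons named by score alone, for neurons of at least 5000 UMIs and without clusters mostly of 1 library were chosen only after the data were seen. No paired analysis was possible because each group is 1 library, and the raw run r2 for the unlabelled library was not run, since that matrix was not used here. The cause of the shifts below was not tested, unless stated. Values are given in the order iWAT-labelled, eWAT-labelled and unlabelled, or for a pair as first over second.

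With at least 200 genes and no mitochondrial limit, neuron shares were 59.5%, 47.2% and 54.3%, and peptidergic small-diameter-like shares 10.5%, 19.5% and 14.6%. The unlabelled C low-threshold mechanoreceptor-like share was 8.61% and the Mrgprd-like share 3.68%. The Piezo2 ratio to unlabelled neurons was 1.35 for iWAT-labelled and reversed to 0.954 for eWAT-labelled neurons, and that of iWAT-labelled over eWAT-labelled neurons was 1.42. With at least 1000 genes and at most 10% mitochondrial UMIs, neuron shares were 75.7%, 64.6% and 48.9%, and peptidergic small-diameter-like shares 33.0%, 13.7% and 39.3%. C low-threshold mechanoreceptor-like shares were 5.59% in the eWAT-labelled and 18.1% in the unlabelled library, and the unlabelled Mrgprd-like share was 13.0%. Piezo2 ratios were 1.18 and 1.35 over unlabelled neurons and reversed to 0.870 between the labelled libraries, where the mechanically gated channel median was -0.057. With neurons named by score alone, the values of neuron share iWAT-labelled, neuron share eWAT-labelled and neuron share unlabelled were 84.0%, 58.3% and 69.5% under the looser filter and 82.7%, 68.8% and 53.6% under the stricter one. With neurons named cell by cell they were 77.8%, 49.9% and 59.5%.

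At resolution 2, neuron shares were 85.4%, 68.8% and 62.6%, and peptidergic small-diameter-like shares 16.9%, 4.75% and 15.8%. C low-threshold mechanoreceptor-like shares were 16.5% in the iWAT-labelled and 10.7% in the unlabelled library, and the unlabelled Mrgprd-like share was 13.1%. At resolution 0.5, peptidergic small-diameter-like shares were 10.1% in the iWAT-labelled and 13.2% in the unlabelled library, and with doublets kept they were 17.0%, 4.55% and 10.2%. With the subtype named neuron by neuron, Mrgprd-like shares were 6.41%, 2.21% and 13.0%, the eWAT-labelled C low-threshold mechanoreceptor-like share was 11.2%, and peptidergic small-diameter-like shares were 18.3% in the eWAT-labelled and 26.7% in the unlabelled library. In neurons of at least 5000 UMIs, peptidergic small-diameter-like shares were 34.2%, 15.3% and 38.9%, the eWAT-labelled C low-threshold mechanoreceptor-like share was 5.69%, and Mrgprd-like shares were 1.64% in the iWAT-labelled and 13.7% in the unlabelled library. The Piezo2 ratio between the labelled libraries was 1.13 there.

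Without clusters mostly of 1 library, C low-threshold mechanoreceptor-like shares were 28.8%, 13.2% and 16.1%, and peptidergic small-diameter-like shares 19.7%, 10.5% and 21.9%. Mrgprd-like shares were 0.0%, 0.0% and 0.0%, by construction, since all clusters of this subtype were left out. Piezo2 ratios over unlabelled neurons were 1.47 and 1.35, and the mechanically gated channel median of iWAT-labelled over unlabelled neurons was 0.15.

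As a mean over cells, Piezo2 ratios were 1.01 and 1.29 over unlabelled neurons and reversed to 0.785 between the labelled libraries. After free RNA was subtracted, the Piezo2 ratio was 2.22 for iWAT-labelled over unlabelled and 1.92 for iWAT-labelled over eWAT-labelled neurons. Wnt11 reversed to 0.810 in the first pair and Timp1 to 0.598 in the second, under a correction that removes too much in the iWAT-labelled library. With the raw run r1, Piezo2 ratios over unlabelled neurons were 1.19 and 1.11. With median-of-ratios scaling, the Piezo2 ratio was 1.07 for eWAT-labelled over unlabelled and 1.21 for iWAT-labelled over eWAT-labelled neurons. The mechanically gated channel medians of these pairs were -0.22 and 0.23, and the injury median of the second was 1.03.

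With equal weight per neuron subtype, which leaves out unnamed neurons, the Piezo2 ratio was 1.34 for eWAT-labelled over unlabelled neurons and reversed to 0.936 between the labelled libraries. Grid2ip reversed to 0.733 for eWAT-labelled over unlabelled neurons. Posterior Hox medians were -3.58 and -0.62 over unlabelled neurons, the latter with the opposite sign, and the mechanically gated channel median of iWAT-labelled over unlabelled neurons was 0.18. Between the labelled libraries the injury median was 0.39 and the stress median reversed to -0.10. With at least 100 UMIs over the pair, the posterior Hox genes median log2 iWAT-labelled over unlabelled was -2.64 and the injury median of eWAT-labelled over unlabelled neurons was 0.093.

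Of 617 ratios under alternatives for 60 named results (a gene in a pair), 614 kept their direction, for genes picked for the largest ratios. In size, 160 moved beyond the counting interval. In all, 17 reversed or fell under 2-fold, 11 of them with equal weight per subtype. These 11 were, besides Grid2ip, Atp2a3 at 1.21, Itga1 at 1.44, Klhl1 at 1.88, Ryr3 at 1.39 and Ctxn3 at 0.853 for eWAT-labelled over unlabelled neurons, Sez6l at 1.33 and Agtr1a at 0.525 for iWAT-labelled over unlabelled neurons, and Plaur at 1.88, Zfp114 at 0.536 and Col6a5 at 0.738 between the labelled libraries. For iWAT-labelled over unlabelled neurons, Car12 was at 1.31 and Col25a1 at 1.94 as a mean over cells, Agtr1a at 0.549 without clusters mostly of 1 library, and Esr1 at 0.537 after free RNA was subtracted. That correction also raised Ly6a to 366 and Col25a1 to 202 for iWAT-labelled over unlabelled, Col25a1 to 287 for eWAT-labelled over unlabelled, and Ly6a to 116 and Ccl2 to 167 for iWAT-labelled over eWAT-labelled neurons. Of the other results, 248 medians of other lists stayed within their counting interval and 75 moved beyond it. These counts were 50 and 46 for shares of other subtypes and 10 and 19 for Piezo2 levels. For shares of neurons with a Piezo2 UMI they were 6 and 6. Depth limits the shares of neurons with a UMI, which leave out the 380, 190 and 806 neurons with under 2000 UMIs.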

Other observations

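Satellite glia markers were present in neurons of all 3 libraries. Their 13 genes together stood at 2974 CPM in iWAT-labelled, 4308 in eWAT-labelled and 3930.0 in unlabelled neurons, against 78674, 52221 and 75185 in cells outside the neuron clusters. The 12 fibroblast markers stood at 193, 416 and 149 CPM in the same order, against 978, 2691 and 4153 in cells outside the neuron clusters. In near-empty barcodes Piezo2 stood at 167 CPM in the iWAT-labelled, 78.1 in the eWAT-labelled and 143 in the unlabelled library. These lay below the levels summed over all neurons and above those in satellite glia-like cells. They also lay above the levels in peptidergic small-diameter-like and Trpm8 cold-sensing-like neurons of the same library. Of all UMIs, 55.6%, 59.2% and 33.8% lay outside called barcodes, in the matrices named r2, r2 and r1.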
